A study of uncultured marine microorganism with 16 samples.

How the data were processed

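RNA from marine microbial communities of the North Pacific Subtropical Gyre was measured on a 1-colour (Cy3) Agilent microarray with probes for genes of many marine microbes, 1 array per sample and 16 arrays in all. Per the labels' protocols, cells were caught on filters, total RNA was extracted, and Cy3-labelled cDNA was hybridised. The 10 mixing experiment arrays form 5 groups of 2 (Surf_FDW, Surf_Cnt, Deep_FSW, Deep_Cnt and Surf_UDW), and the 6 in situ arrays form a morning and an evening group of 3, with 1 sample of each on 14, 15 and 16 September. The in situ groups were taken from the sample titles and the mixing groups from the water type in the labels. Replicate numbers of the mixing experiment carry no pairing. Nothing in the labels says that the replicates of a group came from separate bottles, so the p-values measure the spread between these samples.

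For each array, per the file headers, Agilent Feature Extraction 11.5.1.1 wrote the scanner intensity of each spot. The processed signal is an intensity from which background was subtracted and which was detrended within the array, per the file headers. The median spot signal and the median local background are intensities with no correction. Further columns hold flags of 0 or 1, another kind of value (other) per the file headers, including the flag for a spot well above background. The authors also deposited log2 values as a table for 19525 gene IDs, with a single value for each. The submitters' processing notes name RMA for it, with no version or settings, and the filter behind its gene IDs is not given in the sources used here. In the deposited log2 values the array medians lay between 3.48 and 3.73, close enough together that the authors must have scaled them between arrays. The correlation across genes between the deposited and the scanner values of the same array was 0.897 to 0.978.

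Each array held 180880 spots, of which 170602 belonged to 83217 probes of 20707 gene IDs, with a median of 4 probes per gene ID (1 to 6). A further 600 spots were negative controls, and 104 names belonged to ERCC spike-ins, synthetic RNAs that are added in set amounts. Those amounts are not given in the sources used here. The sources used here hold gene IDs but no gene name, product or organism, so the lists of functions and taxa that were fixed before the data were examined could not be tested. The rule for named genes was to take, among gene IDs past the threshold, the 8 with the largest rise and the 8 with the largest fall in each of 4 comparisons (3 and 3 in the others), and to name only those with a gene name or product. It named none.

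Gene values were computed from the median spot signal and median local background with limma 3.58.1 in R 4.3.3 (the files were read with the data.table package, version 1.17.8). The steps were normexp background correction with an offset of 50, quantile normalization over the 16 arrays without control spots, log2, and median polish of the probes of a gene ID. The design had named the mean spot signal, which the files used here do not hold. The offset pulls the folds of dim genes towards 1, so folds on the scale of the 75th percentile are given beside the 4 gene IDs first named. A gene ID counted as detected on an array when at least 0.5 of its probes were well above background, and was tested when detected on at least 2 arrays of the fit. This left 15951 gene IDs in the mixing experiment and 16919 in the in situ series.

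Differences were tested with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all gene IDs of a comparison and a threshold of 0.05 on the adjusted p. The 10 mixing arrays shared 1 fit with a mean per group, with 5 residual degrees of freedom, and the comparisons were Surf_FDW with Surf_Cnt, Surf_UDW with Surf_FDW, Deep_FSW with Deep_Cnt, Surf_UDW with Surf_Cnt and Deep_Cnt with Surf_Cnt. The in situ arrays were fitted as evening against morning, and as 3 contrasts between dates with the time of day as a term. Lists of genes from 1 comparison were followed in another whose groups share no array with it. This used limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation. Within the mixing experiment both comparisons came from the same fit and its estimate of the spread of each gene ID. Lists chosen by p-value favour gene IDs with a small estimate, which can raise the calls of members there. Only lists followed into the in situ arrays were tested in a separate fit. The deep-enriched list held gene IDs higher in Deep_Cnt than Surf_Cnt with a log2 difference of at least 1. The risen and fallen lists held all gene IDs that passed in Surf_FDW against Surf_Cnt. Under another scaling or without an array the lists were drawn anew from that fit, so their size differs. Where fewer than 10 gene IDs passed in a direction of Surf_FDW against Surf_Cnt, the 50 with the smallest p were taken instead. This held for the fallen list with spike-in scaling, where 5 gene IDs passed as lower. With the 75th percentile, the deposited table and median centring the lists of the quantile-normalized values were also kept, an alternative chosen after seeing the data. Adjusted p-values of lists are over 2 lists for Surf_UDW against Surf_FDW, over 6 tests for the dates and over 4 tests for the comparisons chosen after seeing the data.

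The comparisons, the lists and most alternatives were chosen before the data were examined. The alternatives were processed signal minus the 75th percentile of each array, the deposited table, no background correction, median centring in place of quantile normalization, quantile normalization per experiment, the mean of probes, no filter on dim genes, detection on all arrays of the fit, eBayes with trend and robust, an absolute log2 change of at least 1, fits on only the 4 arrays compared, blocks for date and slide, no term for the time of day, and leaving out each array in turn. Spike-in scaling, which centres the processed signal on the 80 ERCC names well above background on all arrays, was chosen after seeing the data. So were the 75th percentile scaling combined with a block or with an array left out, the surface-enriched list, and following the risen and fallen lists into Deep_FSW against Deep_Cnt and into evening against morning. The pipeline was tested on simulated data. Of simulated changes of 1 on the log2 scale, 100% were called in Surf_FDW against Surf_Cnt, 76.1% in evening against morning and 23.9% between 16 and 14 September. In each simulation 67 changes of 0.5, 67 of 1 and 66 of 2 were added at once to gene IDs drawn at random, on the quantile-normalized scale with its offset. Many changes at once ease the adjusted threshold for each. The noise was independent between gene IDs and between arrays, with no slide effect. For dim gene IDs a change of 1 on that scale stands for a larger fold, so these shares can overstate the power.

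The arrays lay on 5 slides, read in 3 scans, per the file headers. Surf_FDW and Surf_Cnt shared slide 3, Deep_FSW and Deep_Cnt shared slide 4, and Surf_UDW lay alone on slide 5. Slide 1 held the 14 September morning and 15 September evening samples, and slide 2 the other 4 in situ samples. No gene spot was saturated (0 on each array), and 0.124% to 0.287% of gene spots per array carried an outlier flag. Flagged spots were left out of the gene values computed here and kept only in the detection calls. The number of arrays limits the precision of each value.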

Results

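Transcription in microbial communities of the North Pacific Subtropical Gyre was measured in a mixing experiment and in an in situ series. The mixing experiment combined surface water from 25 m with deep water from 130 m, with n = 2 arrays per group. Surf_FDW was 16 L of unfiltered surface water with 4 L of filtered deep water, and Surf_UDW received 4 L of unfiltered deep water in its place. The surface control, Surf_Cnt, was 16 L of unfiltered with 4 L of filtered surface water. Deep_FSW was 4 L of unfiltered deep water with 16 L of filtered surface water, and its control, Deep_Cnt, was 4 L of unfiltered with 16 L of filtered deep water. The in situ samples were taken at 24 m by a drifting automated sampler, the ESP, on the mornings and evenings of 14, 15 and 16 September, with n = 3 for each time of day. Values are log2 intensities per gene ID after quantile normalization, and gene groups are described by their behaviour because the gene IDs carry no name or organism in the sources used here.

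Depth differed widely between arrays. In the surface mixing samples, 68.9% and 73.6% of the 20707 gene IDs were detected in Surf_FDW, 45.4% and 47.2% in Surf_Cnt, and 81.1% and 61.0% in Surf_UDW. In the deep samples, 21.9% and 26.2% were detected in Deep_FSW and 23.6% and 40.1% in Deep_Cnt. In the in situ series the share was 65.3%, 85.4% and 72.7% on the mornings of 14, 15 and 16 September, and 79.1%, 39.4% and 71.5% on the evenings of the same dates. The median processed signal of a gene spot was between 1.22 times (Deep_Cnt 1) and 17.8 times (ESP_morning 15) the median of the negative controls. On all 16 arrays 2510 gene IDs were detected, and 1730 were detected on none.

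**Figure D1:**
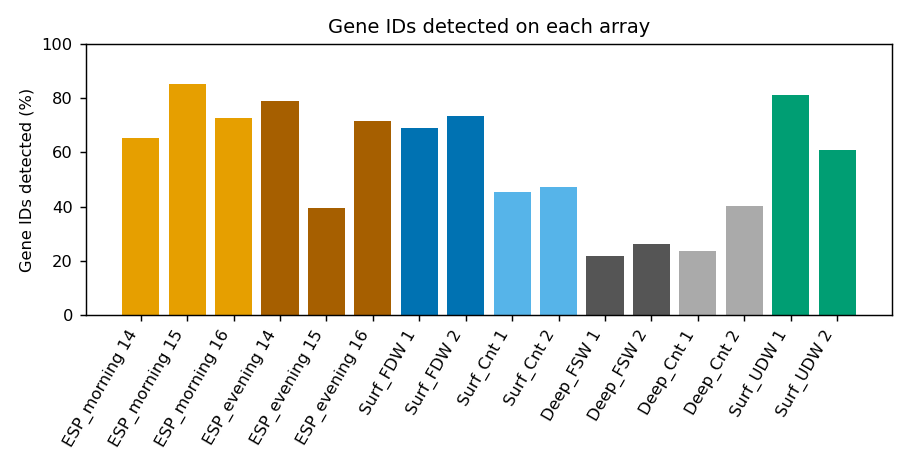
Bars give the percentage of the 20707 gene IDs detected on each of the 16 arrays, coloured by group. The shares ran from 21.9% (Deep_FSW 1) to 85.4% (ESP_morning 15).

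Surf_FDW against Surf_Cnt asked how the surface community responded to the dissolved part of deep water, without its organisms. A group of 155 gene IDs was at least 8-fold higher in Surf_FDW. Its median log2 intensity was 10.11 ± 0.01 (SD, n = 2) in Surf_FDW and 6.43 ± 0.07 (SD, n = 2) in Surf_Cnt, where the median of all tested gene IDs was 6.24. The same group stood at 10.16 ± 0.09 (SD, n = 2) in Surf_UDW and at 9.54 ± 0.46 (SD, n = 6) in situ, but at 6.33 ± 0.13 (SD, n = 2) in Deep_FSW and 6.32 ± 0.01 (SD, n = 2) in Deep_Cnt. Of the 155, between 61.3% and 67.1% were detected on a Surf_Cnt array and 100% on each Surf_FDW array.

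**Figure D2:**
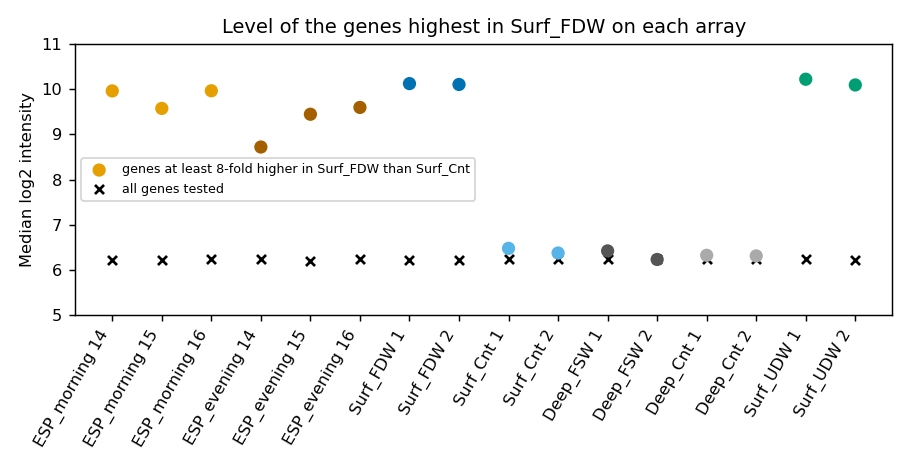
Points give the median log2 intensity, on each array, of the 155 gene IDs at least 8-fold higher in Surf_FDW than Surf_Cnt, and crosses that of the 15951 gene IDs tested in the mixing experiment. The group lay between 8.72 and 9.96 on the in situ arrays, and at 6.48 or lower on the Surf_Cnt and deep arrays.

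Of the 15951 gene IDs tested, 2348 rose and 2401 fell in Surf_FDW (limma), together 29.8%. The rises were the larger changes. Their median was 1.03 on the log2 scale, and 1195 were at least 2-fold, while the median of the falls was −0.43, and 208 were at least 2-fold and 11 at least 8-fold. Of the risen gene IDs, 313 (13.3%) had no probe above background on either Surf_Cnt array. By the detection rule, 53.5% and 49.7% of the risen gene IDs were detected on Surf_Cnt 1 and 2, so the folds of many depend on the background. The largest rise, G0215009307, went from 7.99 ± 0.26 (SD, n = 2) in Surf_Cnt to 15.22 ± 0.10 (SD, n = 2) in Surf_FDW. This was 150-fold (log2 7.23, SE 0.59, limma adjusted p = 2.03e-05), and 587-fold on the scale of the 75th percentile. The next, G0215009299, went from 8.04 ± 0.57 to 14.83 ± 0.01 (SD, n = 2 each), which was 111-fold (limma adjusted p = 2.39e-06), and 354-fold on the scale of the 75th percentile. The largest falls were G0215001776, from 13.98 ± 0.47 to 10.27 ± 0.06 (SD, n = 2 each, 13.0-fold, 3.10-fold on the scale of the 75th percentile, limma adjusted p = 8.86e-07), and G0215001739, from 14.61 ± 0.03 to 10.98 ± 0.0022 (SD, n = 2 each, 12.4-fold, 3.08-fold on the scale of the 75th percentile, limma adjusted p = 9.80e-08). Both falls are absent from the deposited table, and what their probes target is not given in the sources used here. These 4 gene IDs lie outside the rule for named genes and were chosen after their values were seen.

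The rises and falls depended unequally on the scale set between arrays. The median of all tested gene IDs differed by −0.56 with the 75th percentile scaling and by 0.85 with spike-in scaling, against −0.074 after quantile normalization. With the 75th percentile 3338 gene IDs were higher and 7170 lower, with median centring 2625 and 59, and with spike-in scaling 7106 and 5. Both named falls lost their call with median centring (log2 −0.63, limma adjusted p = 0.0745, and −0.55, limma adjusted p = 0.111) and with spike-in scaling (log2 −0.23 and −0.21). The 4 arrays shared 1 slide, and a fit on them alone called 6108 gene IDs (2687 higher, 3421 lower). Without Surf_FDW 1 the count was 2805 (1836 higher, 969 lower), and without Surf_FDW 2 it was 2910 (1846 higher, 1064 lower). It was 7261 with the mean of probes (2737 higher, 4524 lower). Among the 3175 gene IDs detected on all 10 arrays it was 1926, with 242 higher and 1684 lower and the median of all of them at −0.32; this filter removes gene IDs near the floor in Surf_Cnt or on the deep arrays, where many of the risen ones lay.

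**Figure D3:**
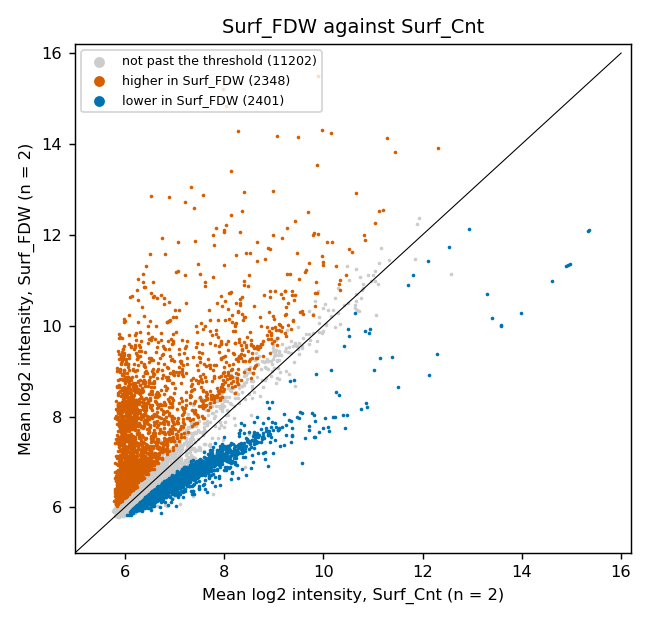
Each point is 1 of the 15951 tested gene IDs, with the mean log2 intensity in Surf_Cnt (n = 2) on the horizontal axis and in Surf_FDW (n = 2) on the vertical axis, and the line marks equal values. The 2348 risen gene IDs reach farther from the line than the 2401 fallen ones, apart from 11 bright gene IDs at least 8-fold lower in Surf_FDW; the falls depend on the scale between arrays (59 with median centring).

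Surf_UDW against Surf_FDW asked what the organisms of the deep water added to its dissolved part. In Surf_UDW 698 gene IDs were higher and 351 lower (limma, 15951 tested). After quantile normalization 86 were at least 2-fold higher, 89 at least 2-fold lower, and none reached 8-fold (0 in each direction), but these sizes depend on the scale. The gene ID with the largest rise went from 8.56 ± 0.23 to 10.35 ± 0.48 (SD, n = 2 each, 3.47-fold, 4.10-fold on the scale of the 75th percentile, limma adjusted p = 0.00521). It lost its call without Surf_FDW 1, where its log2 change was 1.63, against 1.795 with all arrays. The largest fall was 3.03-fold (log2 −1.60, limma adjusted p = 0.00277), but 10.5-fold on the scale of the 75th percentile, with a log2 change of −3.35 in the deposited table and −3.55 with spike-in scaling. The count rested on single arrays: it was 67 without Surf_FDW 1 (28 higher, 39 lower), 260 without Surf_FDW 2 and 445 without Surf_UDW 1. It was 3068 with the 75th percentile scaling (1710 higher and 1358 lower, with the median of all gene IDs at −0.23), 523 in the deposited table and 5 among gene IDs detected on all 10 arrays. With spike-in scaling, where that median was −0.40, 625 were higher and 686 lower. A fit on only the 4 arrays called 713, with 292 higher and 421 lower. Surf_UDW lay alone on its slide, so the deep organisms and the slide cannot be told apart here.

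Genes at different levels in Deep_Cnt and Surf_Cnt were followed in the same comparison. Of the 78 deep-enriched gene IDs, 98.7% were also detected on each Surf_Cnt and Surf_FDW array, so they do not mark deep organisms alone. With the 75th percentile scaling their median level was 2.11 in Deep_Cnt and 1.69 in Surf_Cnt. The 78 deep-enriched gene IDs had a median log2 change of −0.10 in Surf_UDW against Surf_FDW, a mean of 0.026, and a median of −0.020 over all gene IDs (limma's camera, adjusted p = 0.349). Of the 78, 3 rose and 0 fell, and 1 rose when adjusted over the list alone. The list's median relative to all gene IDs was −0.080. The same 78 stood at −0.14 with the 75th percentile scaling and at 0.013 with median centring, with no call in either. The 53 of them in the deposited table stood at −0.33, past the threshold. Drawn anew by the same rule, the list held 2092 gene IDs with the 75th percentile scaling and stood at 0.067, the opposite direction and past the threshold. Without Deep_Cnt 1 the list drawn anew passed it as well (−0.097). The 707 surface-enriched gene IDs, at least 2-fold lower in Deep_Cnt than Surf_Cnt, were a list chosen after seeing the data. Their median change was −0.34, and 164 fell and 5 rose (limma's camera, adjusted p = 1.27e-23). With an estimated correlation the call was lost (limma's camera, adjusted p = 0.239). This list was chosen with the estimate of the spread that the counts of fallen and risen members use, which can raise those counts. No gene ID was detected on all 4 deep arrays and on none of the Surf_Cnt and Surf_FDW arrays (0 by the count of well-above-background flags, with no test).

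Surf_UDW against Surf_Cnt covered the simulated advection as a whole, dissolved part and organisms together. In Surf_UDW 3200 gene IDs were higher and 3571 lower (limma, 15951 tested), 1384 and 252 of them at least 2-fold and 193 and 5 at least 8-fold. G0215009307 was again the gene ID with the largest rise, at 15.21 ± 0.03 in Surf_UDW (SD, n = 2, 149-fold over Surf_Cnt, limma adjusted p = 1.86e-05). The largest fall was 11.9-fold (limma adjusted p = 1.37e-06), and 3.94-fold on the scale of the 75th percentile. It lost its call with median centring (log2 −0.27, limma adjusted p = 0.341) and with spike-in scaling (log2 −0.73). Its gene ID is also absent from the deposited table. With the 75th percentile scaling 3903 were higher and 8756 lower, with the median of all gene IDs at −0.76, and with spike-in scaling 5958 and 44, with that median at 0.49. With median centring 4324 were higher and 2243 lower. Among gene IDs detected on all 10 arrays the count was 2386 (277 higher, 2109 lower, with their median at −0.39), and without Surf_UDW 1 it was 4350 (2553 higher, 1797 lower). Slide and group cannot be told apart in this comparison either.

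Deep_FSW against Deep_Cnt asked how the deep community responded to surface conditions. In Deep_FSW 268 gene IDs were higher and 103 lower (limma, 15951 tested), 65 and 7 of them at least 2-fold and 4 at least 8-fold higher. The gene ID with the largest rise went from 6.20 ± 0.06 to 9.54 ± 0.97 (SD, n = 2 each, log2 3.34, limma adjusted p = 0.00399). On average 0.5 of its 4 probes were above background in Deep_Cnt, so the size of the rise depends on the background, and it was 4.02 without Deep_FSW 1 and 2.66 without Deep_FSW 2. The largest fall was 3.33-fold (limma adjusted p = 8.54e-04). Both lost their call with median centring, where limma called 0 gene IDs (254 at an unadjusted p under 0.05). The fall also lost it with the 75th percentile scaling (log2 −0.99, limma adjusted p = 0.137) and with spike-in scaling (log2 −1.11, limma adjusted p = 0.889). The count was 84 with the 75th percentile scaling (81 higher, 3 lower), 43 with spike-in scaling, 162 in the deposited table and 747 with the mean of probes (453 higher, 294 lower). Both groups shared 1 slide, and a fit on their 4 arrays alone called 49 of the 6035 gene IDs detected on at least 2 of them. The 15951 also hold gene IDs that were not detected on 2 deep arrays. Without Deep_Cnt 1 the count was 586 (289 higher, 297 lower) and without Deep_Cnt 2, the deep array with the most detected gene IDs (40.1%), it was 607 (336 higher, 271 lower).

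The gene IDs that changed in the surface water were also followed here, a test chosen after seeing the data. Of the 2348 risen in Surf_FDW, 32 were higher and 2 lower in Deep_FSW than in Deep_Cnt (limma's camera, adjusted p = 0.893), and adjusted over the list alone 27 and 1. Of the 2401 fallen, 113 were higher and 43 lower (limma's camera, adjusted p = 0.00189), with 236 and 106 adjusted over the list alone. On the deep arrays 74.7% to 87.3% of the fallen gene IDs were detected, but 17.2% to 31.5% of the risen ones. The counts of the risen and fallen lists can therefore not be compared directly. Both lists were also chosen with the estimate of the spread that these counts use, which can raise the counts. The call of the fallen list was lost with an estimated correlation (adjusted p = 0.294), without Deep_FSW 2 (limma's camera, p = 0.145) and without Deep_Cnt 1 (p = 0.375). It was kept with the 75th percentile scaling (relative median 0.082), and lost when the list was drawn anew from that scaling, with 7170 gene IDs (0.0041).

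Deep_Cnt against Surf_Cnt compared the communities in their own water. In Deep_Cnt 1148 gene IDs were higher and 1764 lower (limma, 15951 tested). The lower ones changed more, with 707 at least 2-fold and 98 at least 8-fold lower against 78 and 0 higher. Of the lower gene IDs, 223 (12.6%) had no probe above background on either Deep_Cnt array. By the detection rule, 37.6% and 50.5% of the 707 were detected on Deep_Cnt 1 and 2, so the folds of many depend on the background. The largest fall was from 12.30 ± 0.33 in Surf_Cnt to 6.70 ± 0.01 in Deep_Cnt (SD, n = 2 each, 48.4-fold, limma adjusted p = 4.30e-04). Its log2 change of −5.60 was −9.02 in the deposited table and −4.40 with median centring, so its size depends on the processing. The largest rise was 3.66-fold (limma adjusted p = 2.99e-04), and with median centring the same gene ID was lower in Deep_Cnt (log2 −0.59), while the 75th percentile and spike-in scalings gave no call (log2 0.48 and 0.23). That gene ID is absent from the deposited table. The higher set depended on the scale, with 1 gene ID with median centring (1769 lower), 190 with spike-in scaling (1242 lower) and 4924 with the 75th percentile (1671 lower). Without Surf_Cnt 1 the count was 1660, and a fit on only the 4 arrays called 1504. It was 5181 with the mean of probes (2965 higher, 2216 lower) and 1225 among gene IDs detected on all 10 arrays (694 higher, 531 lower). The groups lay on different slides and cannot be told apart from them.

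Across the 17973 gene IDs compared, correlation did not follow water depth alone. The mean correlation between in situ and Surf_FDW arrays was 0.838 and between in situ and Surf_UDW arrays 0.872, against 0.617 between in situ and Surf_Cnt arrays. Surf_Cnt arrays had a mean correlation of 0.691 with Surf_FDW, 0.764 with Deep_FSW and 0.700 with Deep_Cnt. Over the 2510 gene IDs detected on all arrays, with the 75th percentile scaling, the in situ values were 0.842 with Surf_FDW and 0.662 with Surf_Cnt. Replicates of 1 group correlated at 0.994 in Surf_FDW, 0.971 in Surf_Cnt, 0.952 in Deep_FSW, 0.930 in Deep_Cnt and 0.983 in Surf_UDW. Genes are not independent replicates, and no test was made of these values.

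**Figure D4:**
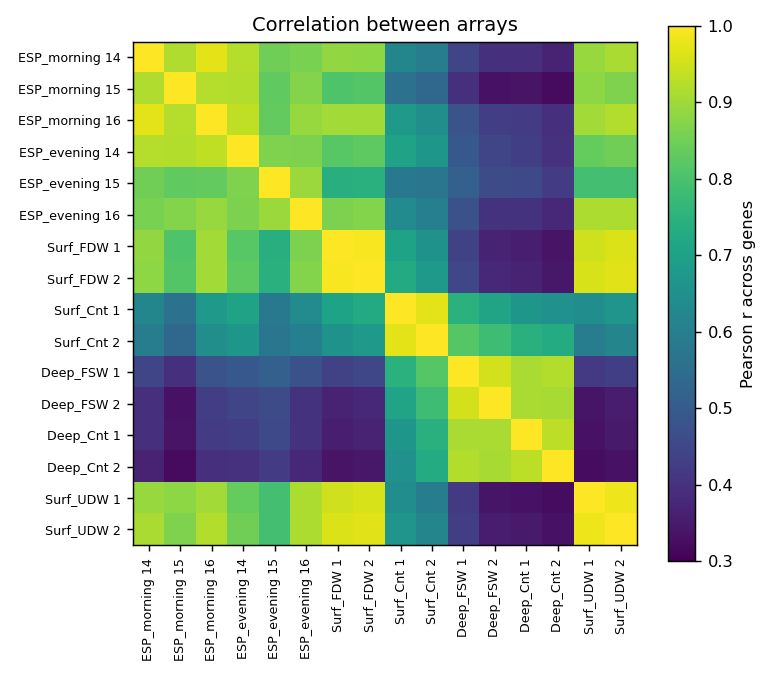
Colour gives Pearson's r across gene IDs between each pair of the 16 arrays, ordered by group. On average the Surf_Cnt arrays lie closer to the deep arrays (mean 0.764 with Deep_FSW and 0.700 with Deep_Cnt) than to the in situ arrays (mean 0.617). Single pairs overlap: Surf_Cnt 1 had 0.704 with ESP_evening 14 and 0.655 with Deep_Cnt 2.

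ESP evening against morning asked what changed in the surface community over the day. Limma called 0 of 16919 gene IDs, with 1131 at an unadjusted p under 0.05 (437 higher and 694 lower in the evening), where the nominal rate gives 846. The 9 other splits of the 6 arrays into groups of 3 gave 126 to 1384, and 2 of them gave more than the real one. The smallest adjusted p from limma was 0.132, and in simulated data of this comparison 76.1% of changes of 1 on the log2 scale were called. That share is for many changes added at once, on the scale with the offset and with independent noise. It can be lower where few gene IDs change, and for 2-fold changes of dim gene IDs. The fitted log2 differences ran from −3.08 to 2.62. With the date as a replicate block limma called 0 (1275 unadjusted), with the slide as a block 0 (1091 unadjusted), and among the 4 arrays of slide 2 also 0 (645 unadjusted). With the 75th percentile scaling it called 213, of which 13 were higher and 200 lower in the evening, 90 with the date as a block and 457 with the slide as a block. In that scaling the count was 2 without ESP_evening 15, the in situ array with the fewest detected gene IDs (39.4%), 0 without ESP_morning 15 or without ESP_morning 16, 122 without ESP_morning 14, 362 without ESP_evening 16 and 573 without ESP_evening 14. After quantile normalization the count was 89 without ESP_evening 14.

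Gene IDs that responded in the mixing experiment were followed over the day, a test chosen after seeing the data. The 2347 tested gene IDs risen in Surf_FDW had a median log2 change of −0.27 from morning to evening, against 0.012 over all gene IDs, and 30.9% of them were above 0 (limma's camera, adjusted p = 1.40e-15). With an estimated correlation the call was lost (adjusted p = 0.294). None of them passed singly (0 by limma over all gene IDs, among the 1131 unadjusted of the whole comparison), and adjusted over the list alone 1 was higher and 7 lower. The 2355 fallen ones had a median of 0.055 (limma's camera, adjusted p = 2.44e-06), lost with an estimated correlation (adjusted p = 0.571). Without ESP_morning 15 the median of the fallen list relative to all gene IDs was −0.0070, and with median centring it was −0.014 for the same gene IDs. Both lists kept their direction without each of the other arrays.

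The contrasts between dates followed the surface community while, per the series' design text, nutrients rose along the drift. Limma called 0 gene IDs in each: 15 against 14 September (974 unadjusted, smallest adjusted p 0.853), 16 against 14 (407 unadjusted, 1.00) and 16 against 15 (1325 unadjusted, 0.582). In simulated data of the 16 against 14 contrast, 23.9% of changes of 1 and 80.3% of changes of 2 on the log2 scale were called, so changes of 2-fold were mostly not detectable with these arrays.

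The gene IDs risen or fallen in Surf_FDW were followed over the dates to ask whether the in situ community moved the same way as the nutrients rose. The 2347 risen gene IDs had a median log2 change of −0.082 in 15 against 14 (limma's camera, adjusted p = 3.59e-07), 0.032 in 16 against 14 (adjusted p = 0.819) and 0.14 in 16 against 15 (adjusted p = 5.10e-07). The 2355 fallen gene IDs had medians of −0.041 (adjusted p = 9.52e-08), 0.066 (adjusted p = 1.41e-07) and 0.11 (adjusted p = 5.48e-18). With an estimated correlation no list passed (adjusted p = 0.966 for the risen list in 16 against 14 and 0.484 for the other 5 tests). No member passed singly in any contrast, over all gene IDs or adjusted over the list alone (0 by limma, with the unadjusted counts of the whole contrasts given above). The risen list's median relative to all gene IDs turned from −0.10 to 0.027 in 15 against 14 without ESP_morning 14, and from 0.14 to −0.034 in 16 against 15 without ESP_evening 16. In 16 against 14 it was −0.030 without ESP_evening 14, −0.14 without ESP_evening 16, 0.15 without ESP_morning 14 and 0.18 without ESP_morning 16. The fallen list's relative median turned from −0.062 to 0.021 in 15 against 14 without ESP_morning 15. It lost its call in 16 against 15 without ESP_morning 15 (0.024), and in 16 against 14 without ESP_evening 14 (0.013) or ESP_morning 16 (0.015). With the same gene IDs under other scalings, the risen list in 16 against 14 stood at −0.15 with median centring, past the threshold in the opposite direction, at −0.017 with the 75th percentile scaling, with no call, and at 0.11 in the deposited table, past the threshold. The fallen list kept its calls in all 3 contrasts with the 75th percentile scaling and in the deposited table, and lost that in 16 against 14 with median centring (−0.0053). Lists drawn anew from each scaling differed more: the risen list in 16 against 14 stood at −0.084 with the 75th percentile (3334 gene IDs), −0.10 with median centring (2624) and −0.073 with spike-in scaling (7024, no call). The fallen list held 54 gene IDs with median centring and lost its calls in all 3 contrasts. With the 75th percentile (6653 gene IDs) it lost them in 15 against 14 and 16 against 15. Only 5 gene IDs passed as lower with spike-in scaling, so gene IDs taken by smallest p stood in for the fallen list. The 40 of these tested in situ gave no call in the 3 contrasts.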

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

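The tests in this part were chosen after the results were seen.

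The ERCC spike-ins, which no comparison between groups uses except as an added scale, stood above the level of the Surf_Cnt arrays (141 and 145, geometric mean of the processed signal) on all 6 in situ arrays, from 617 (ESP_evening 16) to 27217 (ESP_evening 15), a ratio of 44.1. On the mixing arrays they lay between 61.2 and 246.

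The 155 gene IDs at least 8-fold higher in Surf_FDW were near the floor in Surf_Cnt and bright in situ. All 155 were also called higher with each of 6 other scalings and summaries (134 of the 134 present in the deposited table). Those calls use the same arrays from which the 155 were chosen for large rises, so they are not separate evidence. Dimmer Surf_Cnt arrays would lower all bright genes by about 1 factor. Over the 237 gene IDs as bright in Surf_FDW, the interquartile range of the log2 changes was 3.00 after quantile normalization. Of these, 73 rose by less than 2-fold or fell. Quantile normalization takes out a shared factor, so this range alone cannot decide. With spike-in scaling, which leaves such a factor in, the range over the 237 was 3.32. Bright gene IDs thus changed unequally, but list members, chosen for their rise, are among the 237 and widen both ranges. RNA of the deep community in the Surf_Cnt samples would, as the only cause, dilute the genes that are dim on the deep arrays by 1 factor. Over 107 such gene IDs among the 237 the interquartile range was 2.38, and 17 of them rose by less than 2-fold or fell. They thus changed unequally, but list members, chosen for their rise, are among the 107 too and widen the range, so it cannot decide. Deep RNA, alone or beside another cause, stays open. The 78 deep-enriched gene IDs stood at a median log2 intensity of 7.65 in Surf_Cnt, above 6.97 in Surf_FDW, 6.86 in Surf_UDW and 6.77 in situ. With the 75th percentile scaling the values were 1.69 against 0.80, 0.61 and 0.16. Exchanged labels of Surf_FDW and Surf_Cnt cannot be told apart from a response: the in situ arrays correlated at 0.838 with the arrays labelled Surf_FDW and at 0.617 with those labelled Surf_Cnt, which an exchange needs, while Surf_UDW also correlated better with Surf_FDW (0.960) than with Surf_Cnt (0.632), which an effect of deep water would give. A response to the dissolved part of the deep water, which the design names, stays open and untested, since the labels hold no nutrient value per sample.

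Whether the 2401 gene IDs lower in Surf_FDW than Surf_Cnt fell, or others rose more, cannot be told apart. On the spike-in scale their median log2 change was 0.48, but that of all 15951 tested gene IDs was 0.85, against −0.43 and −0.074 after quantile normalization, and such a shift outweighs the falls. That scale assumes equal spike-in amounts, which the labels do not state. With median centring, where all tested gene IDs stood at −0.0097, the median of the 2401 was −0.050 with an interquartile range of 0.121 (0.313 after quantile normalization), and 42 were called lower and 20 higher. With the 75th percentile it was −0.93, and 2116 were called lower and 12 higher. On the spike-in scale 4 of the 2401 were called lower and 145 higher. A lower share of these transcripts among all transcripts, which the design allows, stays open.

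The 213 gene IDs called between ESP evening and morning with the 75th percentile scaling could come from the dim ESP_evening 15 array, without which 2 were called. This cannot be told apart from a loss of power, since 0 were called without ESP_morning 15 or without ESP_morning 16. Of the 10 splits of the 6 arrays into groups of 3, 2 gave as many, the real one included, and the highest other gave 234, with the mornings of 14 and 16 September and the evening of 14 September against the rest. After quantile normalization all 10 gave as many as the real split, at 0 with a highest other of 0. Splits of 6 arrays are too few for a share under 0.05. The log2 change on slide 1, which sets the 15 September evening against the 14 September morning, correlated across gene IDs at 0.631 with the change from morning to evening among the 4 other arrays on slide 2. With the other splits of those 4 arrays into pairs the absolute correlation was 0.414 and 0.106 (with the 75th percentile scaling 0.525 against 0.227 and 0.156). The real split is the highest, but 3 splits are too few for a test and genes are not independent replicates, so a daily change, which the design names, stays open and is otherwise untested.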

How the results depend on the processing

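Spike-in scaling, the 75th percentile scaling combined with a block or a left-out array, and lists kept under another scaling were chosen after seeing the data. Of 287 alternative values for the counts and planned lists, 212 stayed within 1.5 times (counts) or on their side of the threshold (lists), 41 fell below, 23 rose above and 11 reversed. Among the 212 the larger of the higher and lower sets changed in 14 counts, and 3 lists changed sign without a call. The 212 include counts of 0 that stayed at 0, among them all counts between dates. Only totals were compared. Surf_FDW against Surf_Cnt with spike-in scaling (7111 against 4749) thus counted as stayed, though 7106 were higher, 5 lower and 2497 called in both. Of 257 for single gene IDs and added lists, 234 stayed (4 changed sign without a call), 20 lost their call and 3 reversed. The cause was not tested except where the construction shows it (fewer genes, arrays or a stricter call).

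With the 75th percentile, the counts were 10508 for Surf_FDW against Surf_Cnt (main value 4749), 3068 for Surf_UDW against Surf_FDW (1049), 84 for Deep_FSW against Deep_Cnt (371), 12659 for Surf_UDW against Surf_Cnt (6771), 6595 for Deep_Cnt against Surf_Cnt (2912) and 213 for evening against morning (0). Medians relative to all gene IDs, with lists drawn anew from each scaling, were 0.067 for the deep-enriched list (2092 gene IDs, main value −0.080 with 78), −0.084 for the risen list in 16 against 14 (3334 gene IDs, main value 0.017 with 2347), and −0.019 and 0.10 for the fallen list in 15 against 14 and 16 against 15 (6653 gene IDs, main values −0.062 and 0.11 with 2355). With median centring, the counts were 2684, 0 (limma, 254 unadjusted) and 1770 for Surf_FDW, Deep_FSW and Deep_Cnt against their references. The largest rise of Deep_Cnt against Surf_Cnt became −0.59, the risen list −0.10 in 16 against 14 (2624 gene IDs), and the fallen list (54 gene IDs) −0.042, 0.048 and 0.018 in 15 against 14, 16 against 14 and 16 against 15. With the mean of probes, the same counts were 7261, 747 and 5181. Detection on all arrays gave 1926, 5, 2386 and 1225, and a log2 change of at least 1 gave 1403, 175, 1636 and 785, for Surf_FDW against Surf_Cnt, Surf_UDW against Surf_FDW, Surf_UDW against Surf_Cnt and Deep_Cnt against Surf_Cnt; the latter also gave 72 for Deep_FSW against Deep_Cnt. The deposited table gave 523 for Surf_UDW against Surf_FDW, 162 for Deep_FSW against Deep_Cnt, and 0.053 for the risen list in 16 against 14 (2593 gene IDs). Spike-in scaling gave 43 for Deep_FSW against Deep_Cnt and 1432 for Deep_Cnt against Surf_Cnt. Its fallen list (40 gene IDs taken by smallest p, since 5 passed) stood at 0.011, 0.092 and 0.13 in 15 against 14, 16 against 14 and 16 against 15. With the lists kept, median centring gave −0.15 for the risen and −0.0053 for the fallen list in 16 against 14, and −0.014 for the fallen list in evening against morning, and the deposited table gave −0.33 for the deep-enriched list and 0.11 for the risen list in 16 against 14. Only the 4 arrays compared gave 49 of 6035 tested gene IDs for Deep_FSW against Deep_Cnt and 1504 of 9512 for Deep_Cnt against Surf_Cnt. With an estimated correlation the 5 date lists past the threshold kept their medians (−0.10, 0.14, −0.062, 0.052 and 0.11) and lost their calls (p 0.200 to 0.403).

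For evening against morning, the replicate block by date gave 0 (limma, 1275 unadjusted), and with the 75th percentile 90, or 457 with the slide as a block. That scaling gave 122 without ESP_morning 14, 2 without ESP_evening 15, 573 without ESP_evening 14 and 362 without ESP_evening 16.

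Leaving out 1 array at a time, where the lone sample is assumed to vary like the other groups, gave 2805 to 3824 for Surf_FDW against Surf_Cnt, 67 (without Surf_FDW 1) to 1419 for Surf_UDW against Surf_FDW, 254 to 607 (without Deep_Cnt 2) for Deep_FSW against Deep_Cnt, 4350 (without Surf_UDW 1) to 5234 for Surf_UDW against Surf_Cnt, 1660 (without Surf_Cnt 1) to 3366 for Deep_Cnt against Surf_Cnt and 0 (limma, 1131 unadjusted with all arrays) to 89 (without ESP_evening 14) for evening against morning. The relative list medians ran from −0.14 to −0.046 (deep-enriched, past the threshold without Deep_Cnt 1, −0.097), from −0.28 to 0.027, −0.14 to 0.18 and −0.034 to 0.31 (risen, 15 against 14, 16 against 14 and 16 against 15), from −0.11 to 0.021, 0.013 to 0.086 and 0.024 to 0.17 (fallen, same order), and from −0.0070 to 0.072 (fallen, evening against morning). Limma called 0 between dates under every alternative.

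Not run were the lists of functions and taxa, since the gene IDs have no names here. The deep-enriched list drawn anew with median centring was not run either, since too few gene IDs passed. Signal over background limits the deep comparisons, where 21.9% to 40.1% of gene IDs were detected.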

Other observations

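The comparisons with the deposited table in this part were chosen after the results were seen.

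The 11 gene IDs at least 8-fold lower in Surf_FDW than Surf_Cnt were bright on the other arrays. Their median log2 intensity was 10.98 in Surf_FDW and 11.34 in Surf_UDW, against 14.61 in Surf_Cnt, 15.25 in Deep_FSW, 15.37 in Deep_Cnt and 13.95 to 15.95 on the in situ arrays. Their median change in Surf_FDW was −1.62 with the 75th percentile scaling.

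All 11 lie outside the deposited table of log2 values, as do 942 of the 15951 tested gene IDs. Of the 208 gene IDs at least 2-fold lower, 42 lie outside it. Of the gene IDs at least as bright in Surf_Cnt as the dimmest of the 11, 12 lie outside the table, the 11 included, and 6 in it. Since the 11 were chosen for their fall, a test of its link with the table would decide nothing. What the probes of the 11 target is not given in the sources used here. In all, 1182 of the 20707 gene IDs lie outside the table, and 91.8% of them were detected on at least 1 array, against 91.6% of those in it.

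Of the 4330 gene IDs detected on none of the Surf_Cnt, Surf_FDW and deep arrays, 155 (3.58%) were detected on both Surf_UDW arrays. The deviations of same-date morning and evening samples from their group means correlated across gene IDs at 0.0092, −0.014 and 0.234 for 14, 15 and 16 September, and those of different dates at −0.247 to 0.239, the highest being the 14 September morning with the 15 September evening, which shared a slide.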
